A study of Mus musculus with 24 samples.

How the data were processed

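RNA was measured in 24 libraries from grafts of CT26.WT, a colon carcinoma line of Balb/c mouse origin. The labels put 6 libraries in each of 4 groups, formed by host (NSG, an immunodeficient strain, or immunocompetent Balb/c) and diet (0.86% or 0.172% methionine, fed for 3 to 4 weeks). Libraries carry the numbers 1 to 24, which pair nothing across groups, and the labels give no batch. They do not say outright that each library came from a separate animal, so p-values measure the spread between these libraries. The labels also differ on the library kit. The series text names a stranded kit with ribosomal depletion, while the extraction protocol names poly(A) enrichment, so strandedness is not settled and genes with an antisense or overlapping partner are uncertain. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, averaged 5.38 to 6.14 per tumour on the deposited log2 scale, where 4.07 stands for a count of 0. Such low values go with poly(A) enrichment, unless these reads were lost in counting, and leave strandedness open.

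Per the submitters' processing notes, the authors used STAR, featureCounts and DESeq2 with the mm10 build. Their versions, the annotation, and the handling of reads that map to several genes are not given in the sources used here. The deposited values are on a log2 scale, made by the authors with the variance-stabilising transformation of DESeq2, as far as the values show. Their floor was 4.0711, which stood for a count of 0, and their highest value was 19.3186. At the floor lay 51.7% of the values. On this scale a difference approaches a log2 fold change for abundant genes and understates the change of genes with few counts. Inverting the scale gave whole counts, within 0.01, for 100% of the 640012 values above the floor, and the size factors of the libraries were recovered within a relative gap of 3.11e-04. These recovered counts gave the depth of each library and the normalised counts per group. The tests used the deposited log2 values. The table had 55228 lines, of which 26 carried a date in place of a gene name and were left out. Of the 55202 names kept, 53543 matched GENCODE mouse release 21 on mm10, from which coordinates were taken.

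Assigned counts ranged from 31339425 to 57162217 per library, so counting error was small beside the spread between tumours except for genes with few counts. Before averaging, all 276 pairs of libraries were compared. Libraries 19 and 23, and libraries 20 and 24, all of Balb/c hosts on 0.86% methionine, were far closer to each other than any other pair. Each of these pairs was averaged and counted as 1 tumour, which left 22 tumours, 4 of them in that group and 6 in each other group. The design fixed before the data were examined had used all 24 libraries as separate tumours. The change to 22 was settled after the calls of both versions had been seen, on the closeness of the pairs. That closeness is slightly outside pure sampling noise, so the number of genes called with 24 libraries is given for each contrast.

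Genes were tested with limma 3.58.1 in R 4.3.3, as a means model of the 4 groups with a shared spread, eBayes with trend and robust options (statmod 1.5.0), two-sided, and Benjamini-Hochberg adjustment over 38019 genes with a count in any library. The threshold was an adjusted p of 0.05. A value of at least 3 in at least 6 tumours had been set as the filter. Because the floor of the scale lies above it, it removed 0 of the genes that vary. The 5 contrasts were the diet effect (0.172% minus 0.86%) in each host, their difference, and the host effect (Balb/c minus NSG) on each diet. A list of 37 gene sets was fixed before the data were examined. The sets cover methionine and amino acid metabolism, stress responses, the cell cycle, immune and stromal cells, tissues near the graft and RNA quality. Of these, 36 had at least 4 tested members and were tested with limma's fry, adjusted over the lists of a contrast. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The mean of each list per tumour was compared by two-sided exact permutation over 924 splits of 6 against 6 tumours, or 210 splits of 4 against 6, adjusted over lists. The smallest p these allow is 0.00216 and 0.00476.

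Named genes followed a rule fixed beforehand. It takes the 8 largest rises and 8 largest falls among called genes with a mean value of at least 5 in a compared group, leaving out predicted models, pseudogenes and receptor segments. It adds up to 4 members with the smallest adjusted p from each list with a call, and a panel of 28 genes. Genes named outside the rule are marked as chosen after their values were seen. Differences are given with standard errors, and normalised counts with SDs.

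The alternatives chosen beforehand were no filter, a stricter filter (a value of at least 5 in at least 6 tumours), log2(normalised count + 10), centring each library on its median, quantile normalisation, library weights (arrayWeights), eBayes without trend and robust options, a fit on the contrast's groups only, camera with a preset (0.01) or an estimated correlation, list medians, and leaving out each tumour. Count tests by edgeR and DESeq2 were also named beforehand and were not run. Whole counts could be recovered, but the tests kept to the deposited log2 values. Named genes and the genes called for diet were refitted without each tumour in turn, a step added after the data were seen. List and gene values without tumour 17, and without the averaged tumour of libraries 19 and 23, are given because those tumours were seen to stand apart. Chosen after seeing the data were the fits on 24 libraries, on the first or second library of each pair, and with each pair as a random block, a voom fit of the recovered counts, and the mean of both diet effects. Limma and fry were tested on simulated data drawn from the real means for both diet effects and both host effects, but not for the difference between hosts or the mean diet effect, and the permutation tests were not tested so. With a mean of at least 50 counts and genes changed 2-fold, 90% were recovered for diet in NSG, 80% for diet in Balb/c, 74% for the host effect on 0.86% and 78% on 0.172% methionine. At 1.5-fold these shares were 60%, 50%, 48% and 52%. Each simulated contrast held 50 changed genes at each of 1.5-, 2-, 4- and 8-fold, and genes were drawn independently. So many changed genes loosen the adjusted threshold. The shares therefore overstate recovery where few genes are called, as for the diet effects. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the counts, checks and plots.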

Results

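Transcriptomes of CT26.WT grafts were compared between mice fed 0.86% methionine and mice fed 0.172% methionine, in NSG and in Balb/c hosts. NSG hosts lack T, B and NK cells, while Balb/c hosts are immunocompetent and of the strain from which the grafted line derives. The hosts thus differ in immune deficiency, in strain and in whether the graft matches the host strain. The host effects below cannot tell these apart. The title of the series contrasts what methionine restriction does to tumour growth in immunodeficient and immunocompetent mice. Each library from grafts in NSG hosts held 35937162 to 51729669 assigned counts. In Balb/c hosts the range was 31339425 to 42046711 on the restricted diet and 32760046 to 57162217 on the high-methionine diet. Mitochondrially encoded transcripts took 1.82% to 3.12% of the counts, and ribosomal protein genes 5.34% to 8.02%.

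Host identity could be read from strain-dependent genes, which were chosen after their values were seen. The NK receptor gene Klra8 had 20 to 178 counts in every NSG library and 0 to 2 in every Balb/c library. The MHC class II entry H2-Ea-ps had at most 2 counts in NSG libraries and at least 178 in Balb/c libraries. Il2rg and Prkdc, the genes mutated in NSG mice, did not separate the hosts by presence of reads, and the reads of graft and host cells cannot be parted here. Il2rg had 578 to 1895 counts in NSG and 1147 to 2370 in Balb/c libraries, and Prkdc had 392 to 1244 counts over all libraries. Y-linked genes were nearly silent although the labels give male mice, with 38 counts of Ddx3y, Eif2s3y, Kdm5d and Uty over all 24 libraries.

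Among Balb/c grafts on 0.86% methionine, libraries 19 and 23 correlated at r = 0.9987 across 11518 genes and libraries 20 and 24 at r = 0.9981, against at most 0.9921 for the other 274 pairs. Genes are not independent replicates in these correlations. Over genes with 20 to 100 counts the chi-square per degree of freedom was 1.21 and 1.17 for these pairs, slightly above sampling noise, and at least 2.44 for every other pair. Over all genes with 20 or more counts it was 2.60 and 3.96, clearly above sampling noise, and at least 21.6 for every other pair. Each pair was averaged and counted as 1 tumour, which left 4 tumours in that group. For the number of genes called in each contrast, the number with all 24 libraries kept apart is given too, the version planned before the data were examined.

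**Figure D1:**
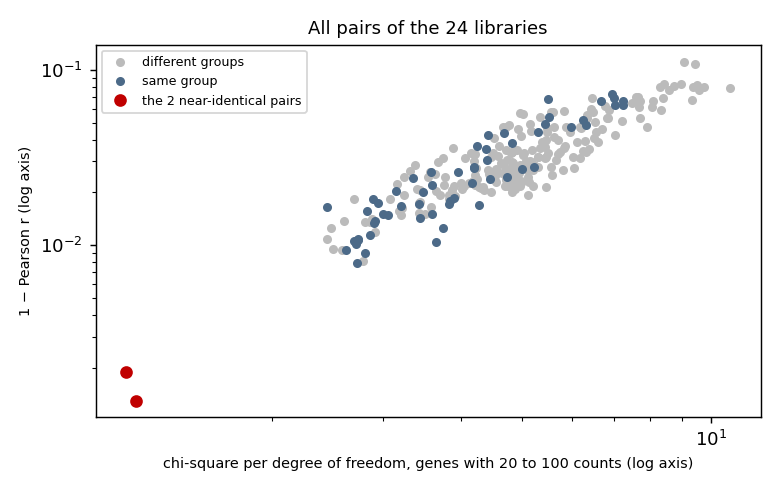
Each point is 1 of the 276 pairs of libraries, with the chi-square per degree of freedom over genes with 20 to 100 counts on the horizontal log axis and 1 minus Pearson's r on the vertical log axis. The 2 near-identical pairs lie at 1.21 and 1.17, and every other pair, within or between groups, lies at 2.44 or higher.

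In NSG hosts, the restricted diet left the tumour transcriptome largely without called changes. Asns, an asparagine synthetase induced by amino acid shortage, had 14510 ± 3830 normalised counts on the restricted and 13240 ± 2190 on the high-methionine diet (SD, n = 6 each). Mat2a, which makes S-adenosylmethionine from methionine, had 9654 ± 1090 and 10260 ± 1390. Trib3, a pseudokinase of the ATF4 response, had 1745 ± 831 and 2649 ± 502, a log2 difference of -0.71 ± 0.23 (SE) that did not pass (limma adjusted p = 0.612). Across the 34 ATF4 targets 0 members passed, and the median difference was -0.10 (fry adjusted p = 0.879).

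The methionine cycle list was not called for diet in NSG hosts, with a median log2 difference of 0.00 over 13 genes (fry adjusted p = 0.957). The transsulfuration and glutathione list was not called (median -0.08, adjusted p = 0.793), with 1 of 16 members lower when adjusted over the list alone. Nor was the polyamine and salvage list (0.05, 0.793), with 1 of 15 higher on that basis. NRF2 antioxidant genes had a list mean of 11.86 ± 0.041 on the restricted and 11.99 ± 0.082 on the high-methionine diet (SD, n = 6 each). Their unadjusted permutation p, 0.00433, was the smallest of the 36 lists and did not pass (exact permutation adjusted p = 0.156). All 13 mitochondrially encoded genes had positive differences, with a median of 0.39. That list had an unadjusted fry p of 0.0246 and an adjusted p of 0.793, and 4 of its members passed when adjusted over the list alone and 0 over all genes. The share of counts from the mitochondrial genome was 2.81 ± 0.244% on the restricted and 2.37 ± 0.445% on the high-methionine diet (SD, n = 6 each).

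At the gene level 2 of 38019 genes passed in NSG hosts and both fell, while 2554 had an unadjusted p under 0.05 against 1901 that chance alone would give. Both genes lie outside the naming rule and were chosen after their values were seen. The predicted gene Gm34719 (chromosome 12, 110046686 to 110086423) fell from 34.3 ± 7.31 to 12.4 ± 2.56 normalised counts (SD, n = 6 each), lower in 6 of 6 tumours than in every tumour on the high-methionine diet (limma adjusted p = 0.036). Acox2, a peroxisomal oxidase gene, had 0 counts in all tumours on the restricted diet and a mean of 1.88 on the other, too few for a fold. Leaving out any 1 of 16 tumours ended the call of Gm34719, and any 1 of 17 that of Acox2 (adjusted p up to 0.132 for both). Fry called 0 of 36 lists. Camera called 6 lists with a preset and 0 with an estimated correlation. With 24 libraries 1 gene passed, and leaving out 1 tumour at a time gave 0 to 2.

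In Balb/c hosts on the restricted diet, macrophage, MHC class II and endothelial markers had lower values, as had red blood cell (median -0.61) and adipose genes (-0.57), and none of these lists passed the adjusted threshold. The macrophage list had a median log2 difference of -0.60 over 17 genes, with 0 members passing over all genes and 7 lower when adjusted over the list alone (fry unadjusted p = 0.0111, adjusted p = 0.257). The MHC class II list had a median of -0.95, with all 9 members lower in the estimate and 0 passing (unadjusted p = 0.0245, adjusted p = 0.257). Endothelial markers had a median of -0.49, with 5 of 15 lower when adjusted over the list alone (adjusted p = 0.257). Without the averaged tumour of libraries 19 and 23 the medians were -0.17 for endothelium, -0.57 for MHC class II, -0.44 for macrophages and -0.02 for red blood cells. The adipose list mean was highest in tumour 22, at 7.04, against 5.50 to 6.24 in the other Balb/c tumours on 0.86% methionine. Adipose list means were also lower on the restricted diet in NSG hosts, by 0.832, against 0.541 in Balb/c hosts (exact permutation adjusted p = 0.628 and 0.539). Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had a median of -0.20, with 4 of 17 lower when adjusted over the list alone (unadjusted p = 0.0294, adjusted p = 0.257). Their list mean was highest in the averaged tumour of libraries 19 and 23, at 6.14, against 5.67 to 5.84 in the other Balb/c tumours on 0.86% methionine. In the host effect at 0.86% methionine that list had a median of 0.24 and 1 of 17 members higher (adjusted p = 0.0819). The macrophage gene Adgre1 had 1443 ± 672 normalised counts on the restricted (n = 6) and 2319 ± 362 on the high-methionine diet (n = 4, SD), a difference of -0.77 ± 0.27 (limma adjusted p = 0.427).

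No lymphocyte list was called for diet in Balb/c grafts, and tumour 17 moved the values of cytotoxic genes. Gzmb, a cytotoxic protease, had 1746 ± 1290 normalised counts on the restricted (n = 6) and 1085 ± 652 on the high-methionine diet (n = 4, SD), a difference of 0.10 ± 0.79 (limma adjusted p = 1). Without tumour 17 it was 0.94 ± 0.40 (adjusted p = 0.694), and that of Prf1 went from 0.45 ± 0.88 to 1.39 ± 0.45 (adjusted p = 0.979 and 0.533). For Cd8a the difference was -0.09 ± 0.47, and for Ifng 0.12 ± 0.19. The T cell list had a median of -0.06 (fry adjusted p = 0.999) and the cytotoxic and NK list one of 0.01 (adjusted p = 0.985). Without tumour 17 these medians were 0.13 and 0.25 (adjusted p = 0.704 and 0.622). Cholesterol synthesis genes were higher in 20 of 21 estimates, with a median of 0.17, 3 higher when adjusted over the list alone and an adjusted p of 0.257. ATF4 targets had a median of 0.17 (adjusted p = 0.675), Asns a difference of 0.30 ± 0.17 and Trib3 one of 0.35 ± 0.26, without a call. Mitochondrially encoded genes had a median of 0.38 (adjusted p = 0.298).

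By limma 1 gene passed for diet in Balb/c hosts, and 2843 had an unadjusted p under 0.05. The gene, chosen after its value was seen, was the antibody segment Ighv9-3, with 0 counts in all 6 tumours on the restricted diet and a mean of 1.37 in the 4 on the other. Fry called 0 of 36 lists, and camera 15 with a preset and 0 with an estimated correlation. With all 24 libraries kept apart 112 genes passed, 30 higher and 82 lower, none of them Ighv9-3. Without tumour 18 the count was 126 genes and 1 list. It was 5 without the averaged tumour of libraries 20 and 24, 4 without tumour 21, 3 without tumour 12, 15, 22 or the averaged tumour of libraries 19 and 23, and 2 without tumour 1, 13 or 14.

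Among the 112, named after their values were seen, the scavenger receptor gene Cd36 had -1.27 ± 0.26 with 24 libraries and -1.27 ± 0.30 with 22 (limma adjusted p = 0.0389 and 0.188). The carnitine palmitoyltransferase gene Cpt1a had -0.61 ± 0.10 and -0.60 ± 0.12 (adjusted p = 0.0137 and 0.158). For Npnt, which encodes the matrix protein nephronectin, the values were 1.11 ± 0.15 and 1.04 ± 0.17 (adjusted p = 0.00317 and 0.057). Kdr, a VEGF receptor of endothelium, had -0.96 ± 0.21 and -0.81 ± 0.23 (adjusted p = 0.0412 and 0.271).

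**Figure D2:**
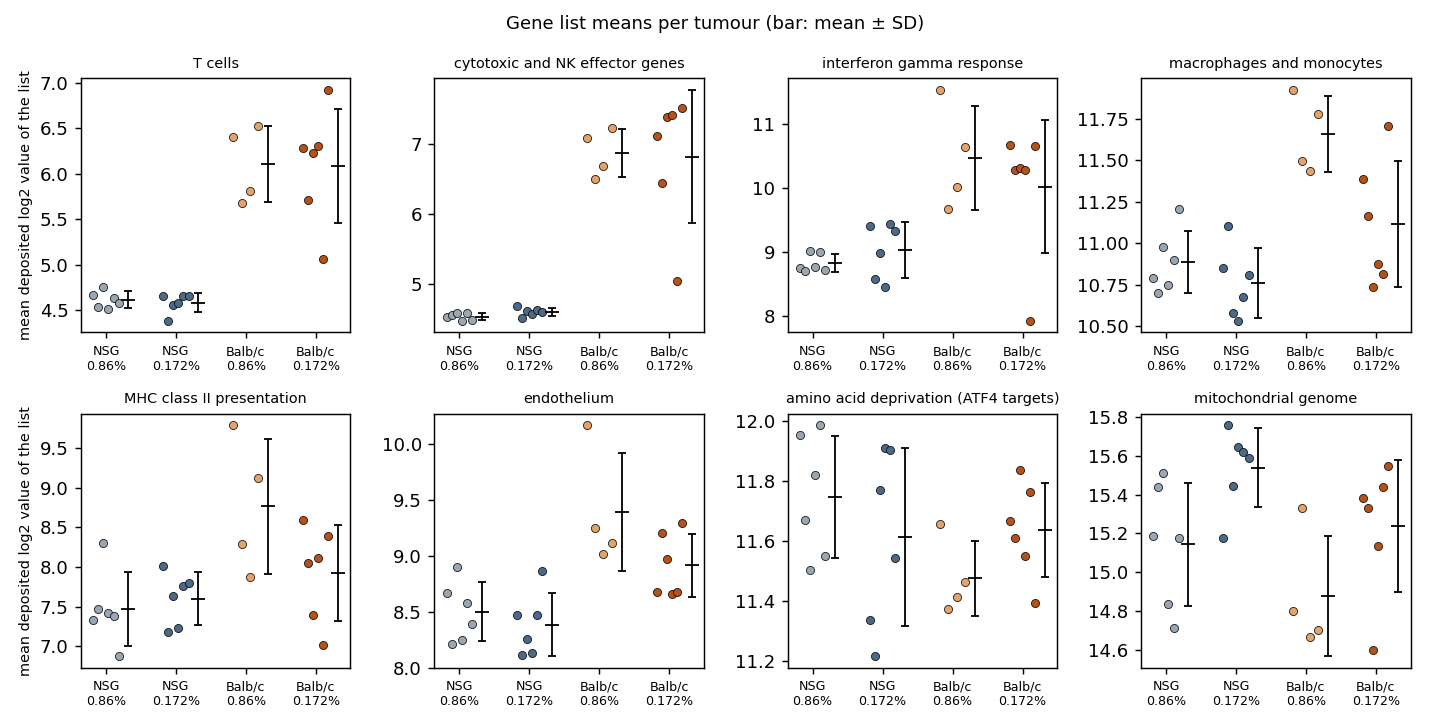
Points are tumours, 6 per group except 4 for Balb/c on 0.86% methionine, and each panel gives the mean deposited log2 value of a gene list. Bars show mean ± SD. T cell means averaged 4.62 and 4.59 in NSG groups and 6.11 and 6.09 in Balb/c groups, for 0.86% and 0.172% methionine.

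Whether the diet acted differently in the 2 hosts was tested by the difference of the diet effects. ATF4 targets had opposite medians, -0.10 in NSG and 0.17 in Balb/c, and the difference for the list did not pass (median 0.22, fry adjusted p = 0.627). Trib3 differed by 1.06 ± 0.35 between hosts and Ddit4 by 0.85 ± 0.34 (limma adjusted p = 0.607 and 0.687). The cholesterol synthesis list had the smallest unadjusted fry p, 0.0177, with a median of 0.35 and 5 of 21 members higher when adjusted over the list alone (adjusted p = 0.477). Dendritic cell markers had a median of -0.46 and MHC class II genes one of -1.25, both with an adjusted p of 0.477.

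Limma called 0 genes for this difference, with 2447 at an unadjusted p under 0.05, a smallest adjusted p of 0.0987 and 0 lists called by fry. Camera called 13 lists with a preset and 0 with an estimated correlation. The voom fit of recovered counts called 1 gene, and the 24-library fit 2, which were Slc22a23 and Ttc33. Leaving out the averaged tumour of libraries 19 and 23 gave 3 genes, and leaving out tumour 5, 13 or 15 gave 1. Across 11510 genes with a mean value of at least 8, the diet effects in the hosts correlated at r = -0.081, over genes that are not independent replicates. A diet effect that differs between hosts was thus not detected in these tumours, which does not show that the hosts responded alike.

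On 0.86% methionine, grafts in Balb/c hosts carried far more T cell, NK cell and cytotoxic transcripts than grafts in NSG hosts. Gzmb rose by 5.71 ± 0.79 on the log2 scale, from 0.469 ± 0.773 normalised counts (SD, n = 6) to 1085 ± 652 (n = 4), higher in 4 of 4 tumours than in any NSG tumour (limma adjusted p = 0.000392). Prf1, which encodes the pore-forming protein perforin, rose by 5.79 ± 0.88 to 1145 ± 812 counts. The T cell receptor constant gene Trbc1 rose from 1.06 to 145.3 counts. Ncr1, an NK receptor gene, had 0 counts in all NSG tumours on this diet and 120.4 in Balb/c tumours. Ifng, with 0 counts in every NSG tumour, averaged 6.98 ± 8.95 in Balb/c tumours (limma adjusted p = 0.0268), and 2.57 without the averaged tumour of libraries 19 and 23 (adjusted p = 0.198).

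Cytotoxic and NK genes rose as a list on 0.86% methionine, with 17 of 19 members higher over all genes and 18 when adjusted over the list alone (fry adjusted p = 3.5e-05, and adjusted p = 0.0166 with an estimated correlation). The 8 largest rises allowed by the naming rule were Gzmg, Gzmd, Gzmf, Gzmc, Prf1, Gzmb, Gzme and Gzma, from 6.57 to 5.09. Several of these granzymes are neighbouring, similar paralogs on chromosome 14 (Gzme to Gzmb, 56117626 to 56262260), so reads may be divided uncertainly among them. In the T cell list 16 of 19 members were higher, 18 when adjusted over the list alone (adjusted p = 8.01e-05, and adjusted p = 0.0166 with an estimated correlation). Cd4 was not among them, at 46.7 counts in Balb/c and 47.9 in NSG tumours, and Cd8a had 43.8 and 1.11 (limma adjusted p = 0.0868), the former 23.2 without tumour 22.

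Regulatory T cell genes rose in Balb/c hosts, with 4 of 8 members higher and 6 when adjusted over the list alone (fry adjusted p = 3.5e-05, and adjusted p = 0.0162 with an estimated correlation). Foxp3, their lineage factor, went from 2.85 to 15.97 counts, and Il2ra, the high-affinity IL-2 receptor chain, from 15.4 to 154.3. Checkpoint genes rose too, with 5 of 13 higher and 10 when adjusted over the list alone (adjusted p = 0.000523, and adjusted p = 0.0187 with an estimated correlation). Pdcd1, which encodes PD-1, rose by 1.48 ± 0.28 and Ctla4 by 1.82 ± 0.47 (limma adjusted p = 0.00366 and 0.0408). Cd274, which encodes the PD-1 ligand, had a difference of 0.96 ± 0.28 that did not pass (adjusted p = 0.0779).

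Interferon gamma response genes were called higher by fry on 0.86% methionine, with 4 of 18 members passing over all genes and 17 when adjusted over the list alone (adjusted p = 0.00977). That call was lost with adjusted p = 0.0999 with an estimated correlation. The T cell chemoattractant gene Cxcl9 rose 67.1-fold in normalised counts, from 29.7 ± 13.9 to 1991 ± 1690 (SD, n = 6 and 4), a log2 difference of 4.47 ± 0.79. Without the averaged tumour of libraries 19 and 23 the rise was 43.1-fold and still passed (limma adjusted p = 0.0225), and without that of libraries 20 and 24 the log2 difference was 5.39. MHC class II genes had 2 of 9 members higher, H2-DMa at 1.57 ± 0.27 and the transactivator Ciita at 1.41 ± 0.33, and 8 when adjusted over the list alone (fry adjusted p = 0.00632, and adjusted p = 0.0769 with an estimated correlation). MHC class I genes had 3 of 11 higher, among them the immunoproteasome gene Psmb8 at 1.23 ± 0.32, and 9 when adjusted over the list alone (adjusted p = 0.0238, and adjusted p = 0.148 with an estimated correlation).

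Endothelial genes had 9 of 15 members higher in Balb/c hosts on 0.86% methionine and 14 when adjusted over the list alone (fry adjusted p = 0.0019, and adjusted p = 0.0615 with an estimated correlation). Pecam1 rose 2.81-fold, from 905.1 to 2546 counts, and Cdh5, which encodes VE-cadherin, 2.13-fold. Macrophage genes had 3 of 17 higher, Ccr2 3.90-fold, C1qc 1.85-fold and Cd163 2.29-fold, and 12 when adjusted over the list alone (adjusted p = 0.00622, and adjusted p = 0.0735 with an estimated correlation). Adgre1 did not pass (limma adjusted p = 0.617). B cell genes had 2 of 15 higher, Blk and Igkc, and 4 when adjusted over the list alone (adjusted p = 0.00678, and adjusted p = 0.0735 with an estimated correlation). Dendritic cell genes had 3 of 13 higher, Itgax, Ccr7 and Batf3, and 5 when adjusted over the list alone (adjusted p = 0.0258, and adjusted p = 0.148 with an estimated correlation).

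Falls in Balb/c hosts on 0.86% methionine were fewer and smaller. Klra8 fell by 2.51 ± 0.26 and the monocarboxylate transporter family gene Slc16a14 by 2.35 ± 0.21, from 76.0 to 2.42 counts, or 0.199 without the averaged tumour of libraries 20 and 24 (limma adjusted p = 4.06e-06 and 2.3e-07). Nqo1, an NRF2 target that detoxifies quinones, went from 467.1 ± 399 to 79.2 ± 51.1 counts (adjusted p = 0.0377), and Gclc, the catalytic subunit of the first step of glutathione synthesis, fell by 0.49 ± 0.10 (adjusted p = 0.00712). The NRF2 list as a whole was not called by fry, with a list mean of 11.91 in Balb/c and 11.99 in NSG tumours. Of the ATF4 targets 3 of 34 fell over all genes, Ddit3 by 0.85 ± 0.20, Vldlr by 0.82 ± 0.19 and Sesn2 by 0.60 ± 0.15. The list did not pass (fry adjusted p = 0.14), with 5 lower and 1 higher when adjusted over the list alone. Other falls under the rule were Taf7l, Ndst4, Slc37a1, Zfp990 and Dhrs9, from -1.76 to -1.26.

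Limma called 963 genes for the host effect at 0.86% methionine, 779 higher and 184 lower in Balb/c. Of these, 322 differed by at least 1 on the deposited log2 scale, which can miss 2-fold changes of genes with few counts. Fry called 11 lists, all higher, 17 without the averaged tumour of libraries 20 and 24, and 15 with 24 libraries. Exact permutation of list means also called 11, at adjusted p from 0.019 to 0.0468. With 24 libraries 1824 genes passed, 947 of them among the 963, and without the averaged tumour of libraries 19 and 23 the count was 526, without tumour 22 it was 620. Library weights gave 1673. With an estimated correlation camera called 4 lists: T cells, cytotoxic and NK genes, checkpoints and regulatory T cells.

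Of 71 named calls on 0.86% methionine, the panel included, 34 passed whichever tumour was left out and 37 did not, and 0 changed direction. The granzymes, Prf1, Trbc1, Ncr1, Foxp3, Pdcd1, Cxcl9, H2-DMa, Pecam1, Cdh5, Gclc, Klra8 and Slc16a14 were among the 34. Without the averaged tumour of libraries 19 and 23 the calls of Ccr2, Batf3, Taf7l and Zfp990 were lost (limma adjusted p = 0.0691, 0.129, 0.0631 and 0.11). Those of C1qc, Ciita, Igkc and Ccr7 were lost without it or without tumour 22 (adjusted p up to 0.0871, 0.125, 0.128 and 0.0761). Itgax was lost without tumour 22 (0.052), Ddit3 without the averaged tumour of libraries 20 and 24 (0.0681), and Vldlr without either averaged tumour (up to 0.0621). Ifng was lost without tumour 8, 22 or that of libraries 19 and 23 (up to 0.198), and Dhrs9 without tumour 10, 21 or the same averaged tumour (up to 0.142). Leaving out any 1 of 6 tumours ended the calls of Nqo1 and Sesn2 (up to 0.113 and 0.0807), any 1 of 8 that of Il2ra (0.129), of 11 that of Cd163 (0.234), of 14 that of Ndst4 (0.248), and of 15 those of Ctla4 and Psmb8 (0.161 and 0.242).

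**Figure D3:**
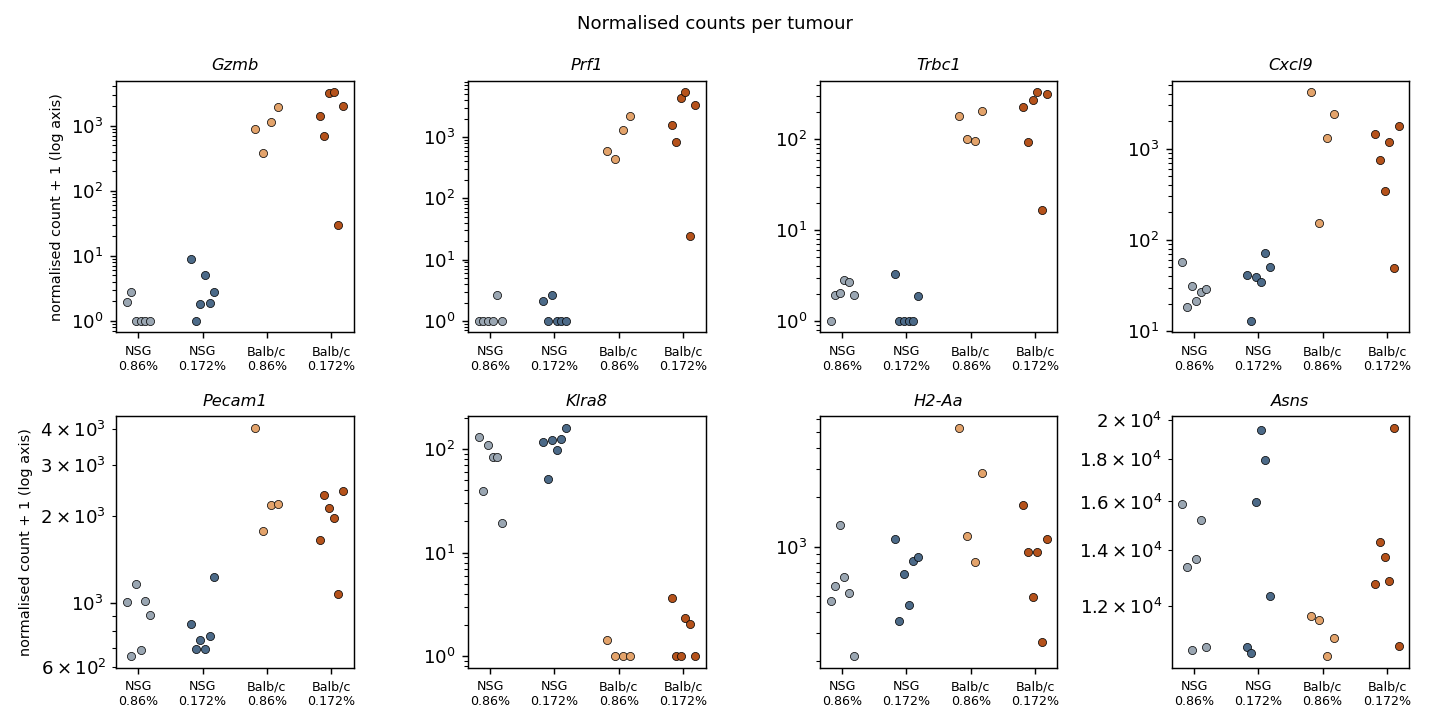
Normalised counts plus 1 per tumour, on log axes, for 8 genes, with 6 tumours per group except 4 for Balb/c on 0.86% methionine. Gzmb, Prf1 and Trbc1 lie above every NSG tumour in all Balb/c tumours, and Klra8 lies below every NSG tumour in all of them.

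The same contrast on 0.172% methionine gave the T cell, NK and checkpoint rises again. Gzmb rose by 5.48 ± 0.70, from 2.58 ± 2.95 to 1746 ± 1290 normalised counts (SD, n = 6 each), higher in 6 of 6 tumours than in any NSG tumour (limma adjusted p = 0.000148). Prf1 rose by 6.18 ± 0.79 and Gzma by 4.81 ± 0.53. Without tumour 17 these 3 rises were 6.32, 7.12 and 5.47. The checkpoint gene Havcr2, which encodes TIM-3, rose 3.39-fold to 578.1 ± 209 counts, and Il2ra 19-fold. Havcr2 had 111.9 to 221.4 counts in NSG tumours on this diet, whose hosts lack T and NK cells. Its rise need not come from T cells. Cd8a went from 0.901 to 57.9 ± 88.7 counts (adjusted p = 0.0456), the latter 22.5 without tumour 18, a call lost on leaving out any 1 of 16 tumours (adjusted p up to 0.0977). Cd274 rose 2.17-fold (adjusted p = 0.027). The mast cell tryptase gene Tpsab1 rose 13.7-fold, from 59.5 to 813.7 counts (adjusted p = 5.52e-05), and the mast cell receptor gene Kit 2.92-fold.

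On this diet 18 of 19 T cell genes, 17 of 19 cytotoxic and NK genes, 8 of 13 checkpoint genes and 4 of 8 regulatory T cell genes were higher over all genes. Adjusted over the list alone, 18, 18, 10 and 7 were. Fry adjusted p was 2e-05 for the T cell, cytotoxic and regulatory lists and 2.11e-05 for checkpoints, and adjusted p = 0.0089 with an estimated correlation in each. Endothelial genes had 6 of 15 higher and 9 when adjusted over the list alone (adjusted p = 0.041, and adjusted p = 0.258 with an estimated correlation), with Pecam1 2.34-fold higher. MHC class I genes had 2 of 11 higher, Nlrc5 and H2-K1, and 9 when adjusted over the list alone (adjusted p = 0.0419, and adjusted p = 0.258 with an estimated correlation). Centring each library on its median ended the endothelial and MHC class I calls, and quantile normalisation the endothelial call and that for G2 and mitosis. Without tumour 3, 4, 14, 18 or 21 fry called 4 lists.

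Genes of G2 and mitosis were lower in Balb/c hosts on the restricted diet, with a median of -0.27 and all 18 estimates negative (fry adjusted p = 0.041, and adjusted p = 0.258 with an estimated correlation). Of these 1 fell over all genes, the spindle checkpoint gene Bub1b, by 0.35 ± 0.09 (limma adjusted p = 0.0383), and 10 when adjusted over the list alone. The proliferation marker Mki67 was not called, with a difference of -0.11 ± 0.19. MHC class II, macrophage, dendritic, B cell and interferon gamma lists, called on 0.86% methionine, were not called here (adjusted p = 0.471, 0.185, 0.995, 0.408 and 0.167). For the interferon gamma list this rested on tumour 17, without which its median went from 0.88 to 1.28 and the list was called (fry adjusted p = 0.000778). The difference between diets in these lists was itself not called, with an adjusted p of 0.477 for MHC class II genes, 0.626 for macrophages, 0.477 for dendritic cells, 0.477 for B cells and 0.729 for the interferon gamma response.

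The largest falls on 0.172% methionine were Klra8 at -2.81 ± 0.24, Ecrg4, an augurin precursor gene, at -2.28 ± 0.40, and the collagen-binding integrin gene Itga11 at -1.92 ± 0.37. They were followed by Slc16a14 at -1.80 ± 0.18, Klra9, Calml4, the RNA-binding protein gene Igf2bp1 at -1.50 ± 0.18, and the Wnt target and stem cell marker Lgr5, from 22.2 to 0.164 counts, or 0 without tumour 18. Klra8 and Klra9 belong to a family of similar receptor genes that differ between strains, so their counts are uncertain. Limma called 796 genes for the host effect at 0.172% methionine, 548 higher and 248 lower, and 216 differed by at least 1 on the deposited log2 scale. With 24 libraries 746 passed, and with library weights 1394. Centring each library on its median gave 398 higher and 510 lower, so that 43.8% of calls were higher against 68.8%, and without tumour 4 the count was 513. Fry called 7 lists and exact permutation of list means also 7. These shared the T cell, cytotoxic, checkpoint, regulatory and endothelial lists, while permutation called neutrophils (adjusted p = 0.039) and inflammatory cytokines (0.0312) in place of MHC class I and G2 and mitosis.

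Of 54 named calls on 0.172% methionine, the panel included, 38 passed whichever tumour was left out and 16 did not, and 0 changed direction. Leaving out any 1 of 6 tumours ended the call of H2-K1 (limma adjusted p up to 0.0807), any 1 of 7 that of Cd274 (0.0677), and any 1 of 8 that of Bub1b (0.112).

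Host differences overlapped between diets, which share no libraries. Of the genes higher in Balb/c, 331 were called on both diets, against 11.2 expected of independent lists, and of those lower 45, against 1.20. These expectations are too low, because both contrasts use the same estimate of each gene's spread. They also count all 38019 genes, of which 19946 passed the stricter filter. Slc22a23, a transporter gene named after its values were seen, was the 1 gene called in opposite directions. It was lower in Balb/c on 0.86% methionine (-0.85 ± 0.20) and higher on 0.172% (0.71 ± 0.18), with limma adjusted p = 0.0175 and 0.0335. The first call was lost without tumour 22 or the averaged tumour of libraries 19 and 23 (adjusted p up to 0.109), and the second on leaving out any 1 of 7 tumours (up to 0.0849). Its diet difference between hosts was 1.55 ± 0.27 (adjusted p = 0.0987 with 22 tumours and 0.0201 with 24 libraries).

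**Figure D4:**
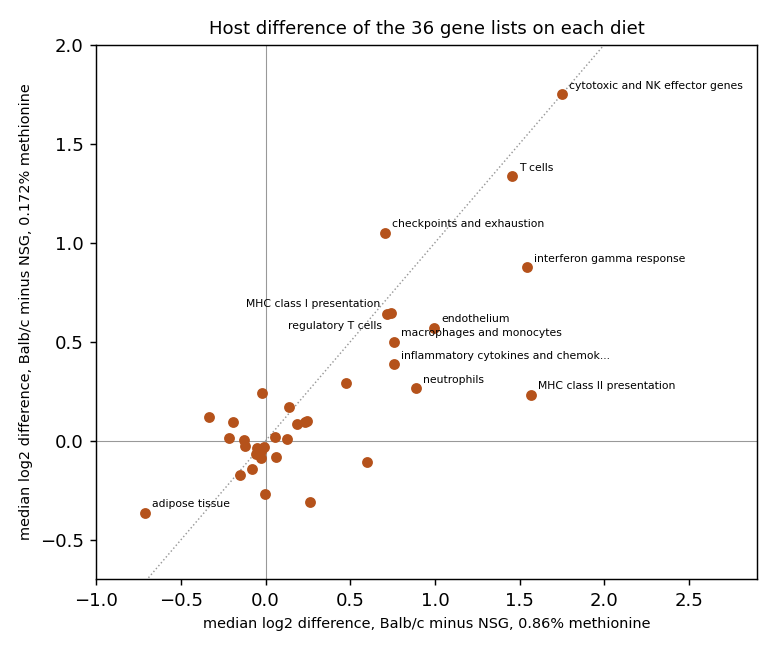
Each point is 1 of 36 gene lists, with its median log2 difference (Balb/c minus NSG) on 0.86% methionine on the horizontal axis and on 0.172% methionine on the vertical axis; the dotted line marks equal values. Cytotoxic and NK genes lie at 1.75 on both axes, and MHC class II genes at 1.57 and 0.23.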

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

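The tests of the near-identical libraries and of the Y-linked genes, and the strain-gene test of tumour 17, were chosen only after the result was seen; those on other splits of the samples and on the host-cell lists of tumour 17 were set beforehand. Of 168 groups of values, 16 held a tumour far from the others, where chance gives about 1 in 20, or 8.4. Tumour 19 below stands for the mean of libraries 19 and 23, and tumour 20 for that of libraries 20 and 24.

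Tumour 17, from a Balb/c host on 0.172% methionine, had the lowest mean of the interferon gamma response list in its group, 7.93 against 10.28 to 10.67 in the other 5 tumours, and of the MHC class I list, 11.51 against 12.6 to 12.93. Its T cell list mean was 5.07 (others 6.29 ± 0.43, SD) and its cytotoxic and NK mean 5.05 (others 7.17 ± 0.43), with 27 counts of Gzmb against 346 to 3206 in other Balb/c libraries. An NSG tumour under a Balb/c label is argued against by 178 counts of H2-Ea-ps, where NSG libraries had at most 2, and by 1 count of Klra8. Fewer host cells of every kind, as the whole cause, are argued against too: 0 of 3 lists had a lower mean than in each other tumour of the group, with macrophages at 10.82 (others 11.18 ± 0.39), endothelium at 8.68 (8.96 ± 0.29) and fibroblasts at 11.62 (11.42 ± 0.35). A smaller loss of host cells stays open, since Ptprc (657 counts, other Balb/c libraries 716 to 2510) and Pecam1 (1069 normalised counts, other Balb/c tumours at least 1644) were lowest there, and no biological explanation was tested.

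The pairs of libraries 19 and 23, and 20 and 24, were far closer than other tumours of the same group. The pairs were picked as the closest, so it was fixed in advance that the other pairs lie above them. Only the size of the gap argues against separate tumours that are alike through host and diet. Over genes with 20 to 100 counts the lowest chi-square per degree of freedom of the other pairs was 2.443, against at most 1.212. A random share of the reads of 1 library deposited again is argued against by a chi-square of at least 2.6 in both pairs over genes with 20 or more counts. With 1.212 as the higher value of the pairs over genes with 20 to 100 counts, 2 libraries made from 1 tumour remain a candidate explanation. The labels do not state it, and no biological explanation was tested.

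The labels give male mice, and 38 counts of Ddx3y, Eif2s3y, Kdm5d and Uty were found over all libraries. Y-chromosome genes left out of counting altogether are argued against by 36 of 1562 entries on that chromosome with a count, Kdm5d (24), Uty (12) and Ddx3y (2) among them. A single entry held 193268 of the 222152 counts there, and whether those reads were placed rightly was not tested. Too few host cells are argued against by at least 624 counts of the leukocyte gene Ptprc or of Pecam1 in each library. The 4 Y-linked genes had 0.584 counts per 1000 of Ptprc and Pecam1, which is consistent with host cells that lack a Y chromosome, while Xist had 726 to 4820 counts per library. The sex of the grafted cells is not given, so Xist does not settle the sex of the hosts, and no biological explanation was tested.

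Other tumours far from their group were not weighed. Among Balb/c tumours on 0.86% methionine, tumour 19 was highest for polyamines and methionine salvage, at 11.49 against 11.26 to 11.29, and lowest for methyltransferases, at 10.88 against 11.19 to 11.24. Tumour 21 was lowest for transsulfuration and glutathione, at 8.68 against 8.86 to 8.88. Tumour 20 had 2.73% of counts from mitochondrially encoded genes, against 1.996% to 2.075%. On 0.172% methionine tumour 16 was highest for skeletal muscle genes, at 7.30 against 5.55 to 5.71.

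In NSG hosts on 0.86% methionine, tumour 12 was lowest for the nuclear respiratory chain, at 11.83 against 11.92 to 11.96, highest for inflammatory cytokines, at 8.29 against 7.50 to 7.77, and had 26320 genes with a count against 27060 to 27320. Tumour 8 was lowest for red blood cell genes, at 7.40 against 8 to 8.34. On 0.172% methionine tumour 2 was lowest for T cell genes, at 4.39 against 4.56 to 4.66, and had 8.02% of counts from ribosomal protein genes against 6.10% to 6.58%. Tumour 6 was highest for neutrophil genes, at 6.02 against 5.40 to 5.61, and for skeletal muscle genes, at 6.71 against 5.49 to 5.72. Tumour 3 was highest for adipose genes, at 7.69 against 5.28 to 6.18.

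Of 100 drawn splits of the tumours, the real one included, 1 gave as many genes as the host effect on 0.86% methionine (963, highest other split 90) and 1 as many as that on 0.172% (796, highest other 375). For lists these were 2 (11 lists, highest other 12) and 3 (7 lists, highest other 7). No other drawn split reached the gene counts, which argues against chance for the genes of both host effects. The shares for lists lay under the limit set beforehand. Other splits called as many lists or more, however, so chance is not excluded for the list counts. For the 2 genes of the diet effect in NSG hosts 4 of 100 splits gave as many (highest other 6). That share also lay under the limit set beforehand, but another split called more genes, so chance is not excluded. Centring, quantile normalisation and random blocks called 0. For the single gene of the diet effect in Balb/c hosts 46 splits gave as many, and for the 0 genes of the difference between hosts, and the 0 lists of each diet effect and of that difference, 100 did. The highest other splits gave 192 genes in Balb/c hosts and 77 for the difference, and 2, 7 and 3 lists for NSG, Balb/c and the difference. Some drawn splits thus called more genes or lists than the real one, and the reason was not tested.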

How the results depend on the processing

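The fits on 24 libraries, with random blocks, on the first or second library of a pair, and by voom were chosen only after the result was seen, as was the averaging of the pairs itself, which was settled with both sets of calls known. Among 118 named calls 0 changed direction under the 6 alternatives run on them (24 libraries, library weights, median centring, log2 of the normalised count + 10, quantile normalisation and the groups compared alone), and 96 (only the groups compared) to 117 (log2 of the normalised count + 10) stayed past the threshold. Of the 28 panel genes 0 to 4 changed sign per contrast and alternative, the largest with a size of 0.335, in the diet effect in Balb/c with library weights.

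For diet in NSG hosts (2 genes), 1 gene passed with the stricter filter, log2(+ 10), 24 libraries, 24 libraries with the stricter filter, and voom, and 0 with median centring, quantile normalisation, random blocks, the second library of each pair, and the groups compared alone. Leaving out 1 tumour at a time gave 0 to 2. For diet in Balb/c hosts (1 gene), 112 passed with 24 libraries, 249 with the stricter filter besides, 4 with library weights and 2 with quantile normalisation. There were 0 with the stricter filter, centring, random blocks, the first or second library of each pair, voom, and the groups compared alone, and leaving out 1 tumour gave 1 to 126. For the difference between hosts (0 genes), 2 passed with 24 libraries, 8 with the stricter filter besides, and 1 each with the stricter filter, library weights, plain eBayes and voom, with 0 to 3 on leaving out 1 tumour. The cause was not tested, except that treating near-identical libraries as separate tumours adds samples with little spread.

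The host effect at 0.86% methionine (963 genes) rose to 1824 with 24 libraries, 2250 with the stricter filter besides and 1673 with library weights, and ranged from 526 to 1157 on leaving out 1 tumour. For the host effect at 0.172% methionine (796 genes) library weights gave 1394, and leaving out 1 tumour 513 to 1115. Random blocks, with a consensus correlation of 0.914, gave 817 and 644 genes, of which 774 and 617 were shared with the main calls. Camera with a preset correlation called 6, 15 and 13 lists for diet in NSG, diet in Balb/c and their difference, and 22 and 19 for the host effects. With an estimated correlation it called 4 for each host effect. Leaving out 1 tumour gave 0 to 1 lists for diet in Balb/c, and 10 to 17 and 4 to 8 for the host effects. The cause was not tested.

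The edgeR and DESeq2 fits set beforehand were not run: the tests kept to the deposited log2 values, and the recovered counts were fitted with voom alone. The filter against none gave no value, since the filter removed no gene that varies. No paired analysis was possible because the library numbers pair nothing. Depth limits genes with few counts, whose differences the deposited scale understates.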

Other observations

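The mean of both diet effects, which tests a shared diet effect, was itself chosen after the data were seen. Only its bound on the gene count was set before its own value was seen. The test of the mitochondrial genes was chosen only after the result was seen. The mast cell genes Tpsab1 and Kit were higher in Balb/c grafts. Tpsab1, a tryptase gene, rose by 2.26 ± 0.42 on the log2 scale on 0.86% methionine, 6.93-fold in normalised counts, and Kit, the stem cell factor receptor gene, by 1.14 ± 0.25 (SE, n = 4 and 6, limma adjusted p = 0.00366 and 0.0112). Without tumour 22 Kit did not pass (adjusted p = 0.0632). The list of mast cell and eosinophil genes was not called (fry adjusted p = 0.0523 on 0.86% and 0.146 on 0.172% methionine), with 3 and 2 of 14 members higher. Fabp4, a fatty acid carrier of adipocytes and endothelium, rose by 1.37, a call lost on leaving out any 1 of 5 tumours (limma adjusted p up to 0.206), while the adipose list had a median of -0.71 and was not called (adjusted p = 0.748).

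Type I interferon genes were called in no contrast, with a median host difference of 0.26 on 0.86% and -0.31 on 0.172% methionine (fry adjusted p = 0.638 and 0.511). The second value leans on tumour 17, whose list mean was 8.98, against 10.18 to 11.36 in the other Balb/c tumours on that diet. Fibroblast and matrix genes had medians of 0.13 and 0.01 (adjusted p = 0.874 and 0.995), skeletal muscle genes -0.33 and 0.12 (0.325 and 0.964), and genes of the methionine cycle -0.05 and -0.03 (0.289 and 0.964). The skeletal muscle value on 0.172% methionine includes tumour 16, with a list mean of 7.30 against 5.55 to 5.71 in the other Balb/c tumours on that diet.

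A diet effect shared by both hosts was tested as the mean of the diet effects. Limma called 0 genes, with 2737 at an unadjusted p under 0.05 against 1901 by chance and a smallest adjusted p of 0.0551. Fewer than 10 called genes had been set, before this value was seen, to speak against a shared effect. After it was seen that bound was judged too strict, since more genes than chance gives lay under the unadjusted threshold. That excess does not point to a shared effect, because genes move together and the difference between hosts had 2447 such genes. Splits of the tumours were not run for the mean effect. A shared effect was thus not detected, and it stays open. Mitochondrially encoded transcripts had a median of 0.40 (fry unadjusted p = 0.00551, adjusted p = 0.198). Higher mitochondrial transcripts on the restricted diet may thus be present in both hosts, but the test cannot settle it, because its adjusted p missed the threshold and genes of 1 chromosome move together.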
